A study of Homo sapiens with 12 samples.

How the data were processed

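The series holds 12 RNA-seq libraries of KPCR cells in 4 groups of 3. Per the labels' protocols, total RNA was extracted with Trizol, selected for polyA and made into libraries with a stranded kit. Per the submitters' processing notes, Trim Galore, HISAT2, HTSeq and DESeq2 were used, with the mm10 genome build. Their versions and settings, the strand setting of the counting and the annotation release are not given in the sources used here. The labels give the organism as human, but mm10 is a mouse build. Of the counted accessions 0 matched a human RefSeq table, which argues against human as the organism of the counted transcripts.

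The deposited values are counts: whole numbers of reads per versioned mRNA accession, not normalized by the authors as far as the values show, with 29903 accessions in every file and no row for unassigned reads. Totals range from 10178744 to 19331015 per library. The table of human RefSeq accessions used here matched 0 of the 29903, with or without the version, and no other table of names was used. The 49 gene lists and the cell type markers chosen before the data were examined were therefore not tested, nor was the level of Setd5 or of the other genes to be named by symbol. Checks of transcript length and GC content were not run for the same reason. Accessions of near-identical genes may share reads, and reads per accession rather than per gene may split between isoforms.

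Groups were taken from the sample titles. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Accessions were kept by filterByExpr with the 4 groups, which left 9399, and TMM factors were computed. All 12 libraries were fitted together with group as the only term (glmQLFit, robust), because groups of 3 estimate the spread poorly. This assumes 1 spread per accession, shared by the 4 groups. DMSO replicate 1 went against that assumption, with a voom sample weight of 0.151 against 0.673 to 2.24 in the other libraries. Counts of calls from this fit depend on the assumption. The common biological coefficient of variation was 8.43%. Contrasts were tested with glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the kept accessions and a threshold of 0.05. The contrasts were sgSetd5 against sgControl, inhibitors against DMSO, sgControl against DMSO, and the difference of both treatment effects. Standard errors were approximated as the absolute log2 fold change over the square root of the F statistic. CPM values use the TMM-scaled library size, except for the CPM of the set of 94 accessions, which use the total count. Correlations of fold changes used a prior count of 2. Sets called in one comparison were tested in the other with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one.

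The naming rule, chosen before the data were examined, took the 10 accessions highest and the 10 lowest by log2 fold change among those past the threshold, with a mean of at least 5 CPM over the 6 libraries compared and all 3 treated libraries on one side of all 3 controls. Its exclusions by symbol could not be applied. Only the first accession in each direction is printed, because the files do not pair accessions with names. The set of 94 accessions was defined after the data were seen, as those with at most 3 counts summed over DMSO replicates 1 and 2 and at least 10 counts in DMSO replicate 3.

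The fit was tested on simulated data for sgSetd5 against sgControl with 9399 accessions, of which 200 were changed. It recovered 68% of 50 accessions changed 1.5-fold, 70% at 2-fold, 90% at 3-fold and 92% at 4-fold. Of 169 calls, 9 were on unchanged accessions, 5.33%. All simulated libraries were drawn with a common spread per accession, as the fit assumes. The test therefore does not cover data in which a library departs from its group, and no change below 1.5-fold was simulated. Replicates were compared by a chi-square of their counts over accessions with at least 20 counts. Chi-square over degrees of freedom ranged from 2.29 to 35.8, so no pair of replicates was a repeat of one library.

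Alternatives were DESeq2 1.42.0, RLE factors, library size only, no filter, a mean of at least 5 CPM, limma voom, only the 6 libraries compared, the replicate number as a block, a 2-fold minimum, an adjusted p under 0.01, no robust estimate and each library left out. After the data were seen, 5 were added: leaving out the set of 94 accessions, its share as a covariate, 1 surrogate variable from sva 3.50.0, leaving out DMSO replicates 1 and 2, and voom with sample weights.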

Results

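PolyA RNA was profiled in KPCR cells, cell lines that were established from trametinib-resistant pancreatic ductal adenocarcinoma tumours. All 12 libraries came from cells kept on trametinib, a MEK inhibitor, at 0.2 µM. They form 4 groups of 3 libraries. One pair of groups carried a control guide RNA (sgControl) or a guide against Setd5 (sgSetd5). The other pair received the vehicle DMSO, or UNC0638 at 0.6 µM together with RGFP966 at 0.6 µM, which the labels describe as inhibitors of G9a and Hdac3. G9a is a histone H3 lysine methyltransferase, and Hdac3 is a histone deacetylase. The labels do not say whether the 3 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

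Each file listed read counts for 29903 mRNA accessions, and 13897 of these had 0 counts in all 12 libraries. Per the processing notes the genome build was a mouse one, although the labels give the organism as human. DMSO replicate 1 held 19331015 counts. The other libraries held between 10178744 and 11732483. The files do not pair accessions with gene names, so changes are described by accession. The level of the Setd5 transcript in the libraries labelled sgSetd5 was not analysed here, and the loss of Setd5 is taken from the labels.

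Libraries of one group correlated with a Pearson r of 0.976 to 0.991 in log2 CPM (read counts scaled to a common library total) across accessions. The lowest value belonged to DMSO replicates 1 and 3. The first principal component held 39.3% of the variance and set DMSO replicates 1 and 2, at -47.2 and -46.5, apart from DMSO replicate 3 at -7.85. A set of 94 accessions varied between libraries of the same group. It was chosen as near absent in DMSO replicates 1 and 2 but not in DMSO replicate 3. Its differences from DMSO below partly follow from that choice. Without the set, DMSO replicates 1, 2 and 3 lay at -20.17, -21.36 and -12.41 on the first component. On the second they lay at 28.26, 23.29 and 11.25. The separation of DMSO replicates 1 and 2 on the first component thus rested largely on the set. The set took 1.09 and 0.891 CPM in DMSO replicates 1 and 2 and 468 in DMSO replicate 3. In the inhibitor-treated libraries it took 619, 540 and 239 CPM, in sgControl 649, 820 and 986, and in sgSetd5 1241, 946 and 280. Of the 93 members tested with edgeR, 0 were called in either treatment comparison at an adjusted p under 0.05, and 13 were called between the control groups. At an unadjusted p under 0.05 the edgeR counts were 1 with sgSetd5 and 8 with the inhibitors. DESeq2 called 0 and 1, with 0 and 6 at an unadjusted p under 0.05, and limma voom called 0 and 22, with 2 and 86.

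**Figure D1:**
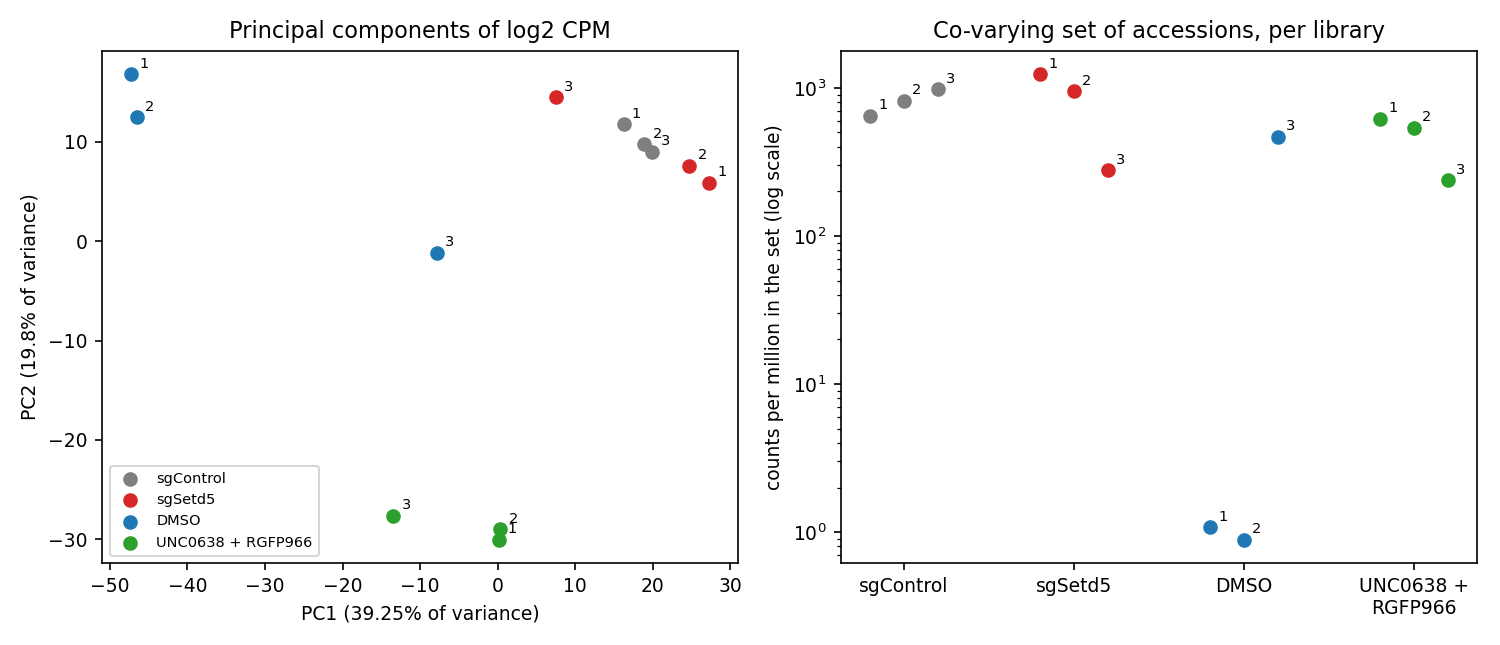
Left, the first and second principal components of log2 CPM for the 12 libraries, coloured by group and numbered by replicate. Right, CPM taken by the set of 94 accessions in each library, on a log scale; DMSO replicates 1 and 2 lie at 1.09 and 0.891, and the other 10 libraries between 239 and 1241.

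The first comparison asked which transcripts depend on Setd5 in cells kept on trametinib. In sgSetd5 cells 352 accessions were higher and 317 lower than in sgControl cells, together 7.12% of the 9399 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes were small, with a median fold of 1.28 among the called accessions. Of those higher, 43 reached 2-fold, against 2 of those lower. The higher calls fell on 75, 149 and 128 accessions in the lowest, middle and highest of 3 equal bins of mean expression, and the lower calls on 9, 75 and 233.

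The accession with the greatest increase under the naming rule was NM_011118.2. It rose from 12.5 ± 2.29 CPM in sgControl to 37.5 ± 1.87 CPM in sgSetd5 (SD, n = 3 each), a log2 fold change of 1.58 with a standard error of 0.117. Its edgeR adjusted p was 3.16e-07. The accession with the greatest decrease was NM_001077707.1, which fell from 10.5 ± 1.33 to 5.65 ± 1.54 CPM (SD, n = 3 each). Its log2 fold change was -0.89 with a standard error of 0.194 and an edgeR adjusted p of 0.00964. That call was lost without sgControl replicate 1 (log2 fold change -0.82, edgeR adjusted p 0.0556) and without sgSetd5 replicate 3 (-0.72, edgeR adjusted p 0.0543).

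The number of calls in this comparison changed with the libraries in the fit. The 669 calls became 1736 without DMSO replicate 1, a library of neither group, and 668 of the 669 were among them. That library can reach this contrast only through the shared spread, the filter and the scaling. With only the 6 libraries of this comparison there were 1865. The 669 calls became 283, 308 and 326 without sgControl replicates 1, 2 and 3, and 370, 285 and 304 without sgSetd5 replicates 1, 2 and 3. Each of these fits leaves fewer libraries in a compared group. That alone can lower the count, so these drops single out no library. With a surrogate variable as a covariate, added after the data were seen, there were 406, and 251 of the 669 were among them. That variable was lower in every sgSetd5 library than in every sgControl library, so it may take out part of this contrast. Scaling by library size alone gave 437 higher and 209 lower, a share of 67.7% higher against 52.6% in the main result.

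The second comparison asked what the combined inhibitors changed on the same trametinib background. With UNC0638 and RGFP966, 552 accessions were higher and 528 lower than with DMSO, 11.5% of those tested (edgeR, adjusted p under 0.05). The median fold among called accessions was 1.40. Of the higher accessions 141 reached 2-fold, and of the lower ones 101. The higher calls were 159, 225 and 168 in the lowest, middle and highest bin of mean expression, and the lower calls 92, 190 and 246.

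NM_008181.3 had the greatest increase under the naming rule, from 0.906 ± 0.354 CPM in DMSO to 16.4 ± 1.32 CPM with the inhibitors (SD, n = 3 each). Its log2 fold change was 4.16 with a standard error of 0.232 and an edgeR adjusted p of 9.23e-10. The DMSO libraries held 18, 14 and 6 counts of it, and the log2 fold change was 4.90 with a standard error of 0.401 when DMSO replicates 1 and 2 were left out, which leaves 1 DMSO library. NM_011607.3 had the greatest decrease, from 57.4 ± 7.82 to 8.58 ± 2.69 CPM (SD, n = 3 each). Its log2 fold change was -2.76 with a standard error of 0.159 and an edgeR adjusted p of 1.06e-08. With only the 6 libraries of this comparison in the fit, the 1080 calls became 704, fewer than the 1865 for sgSetd5 in its own 6. The inhibitors also had fewer calls than sgSetd5 with the replicate block in those libraries, at 835 against 1982. So it was without DMSO replicate 1, at 1373 against 1736, and with voom sample weights, at 1567 against 1812. The order turned without DMSO replicates 1 and 2 too, and in the other alternatives the inhibitors had more calls.

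**Figure D2:**
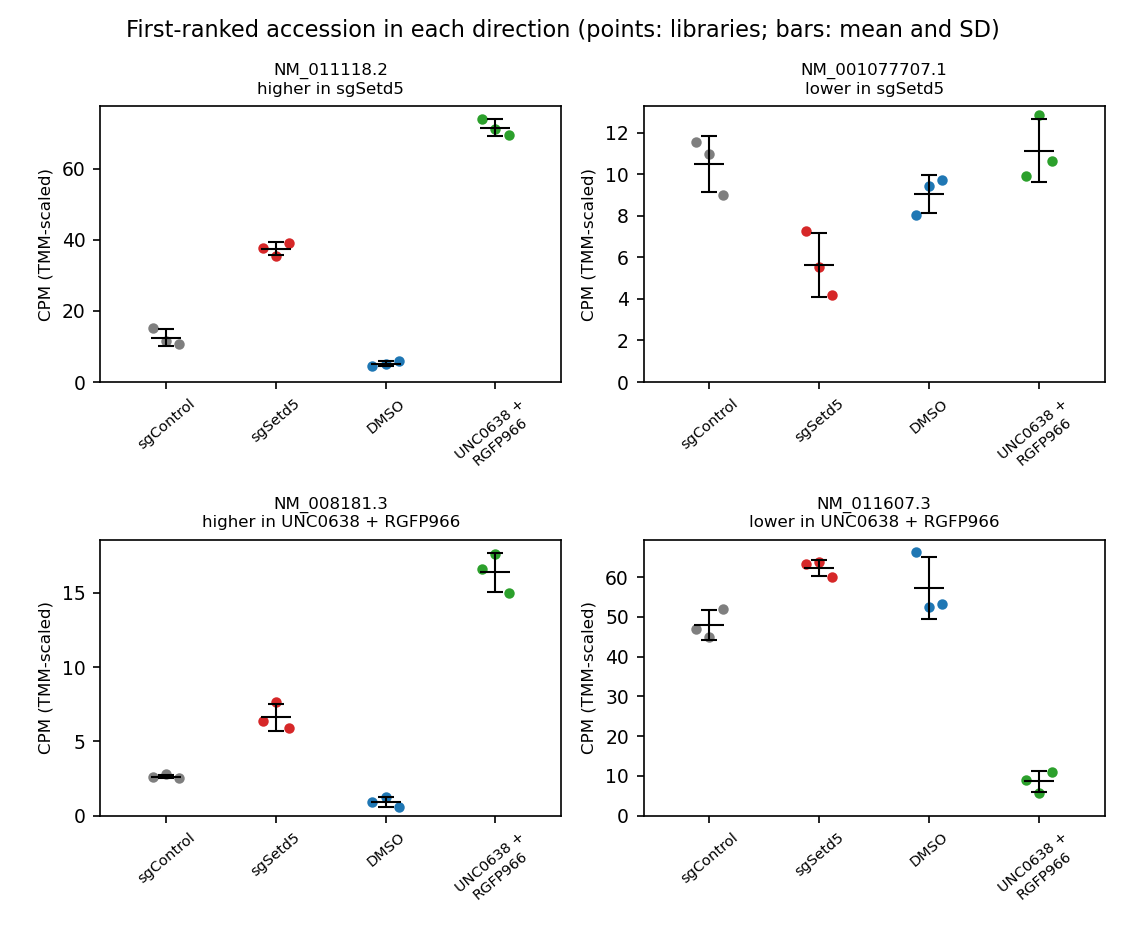
CPM of the first-ranked accession in each direction of each treatment comparison, with a point per library and bars for the mean and SD of each group. NM_011118.2 is higher in all 3 sgSetd5 libraries than in all 3 sgControl libraries, and NM_008181.3 is higher in all 3 inhibitor-treated libraries than in all 3 DMSO libraries.

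The title of the series ties Setd5 to chromatin reprogramming, and the inhibitors act on enzymes of chromatin, so the comparisons were set against each other. They share no library, but in the fit of all 12 libraries they share the estimate of the spread. 193 accessions were called in both, 114 in the same direction and 79 in opposite directions. Independent lists of these sizes would share 38.5 in the same direction and 38.4 in opposite directions. 79 accessions were higher in both, against 20.7 for independent lists (one-sided Fisher's exact p = 1.82e-26), and 35 were lower in both, against 17.8 (one-sided Fisher's exact p = 9.13e-05). The excess extended to accessions higher with sgSetd5 and lower with the inhibitors, 57 against 19.8 (one-sided Fisher's exact p = 2e-13). For accessions lower with sgSetd5 and higher with the inhibitors it was 22 against 18.6 (one-sided Fisher's exact p = 0.236). Accessions are not independent replicates, so these p-values describe the lists.

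Of the 10 accessions with the greatest increase under the inhibitors, 10 had a positive fold change with sgSetd5 and 7 were called there. NM_008181.3 was among them, with a log2 fold change of 1.33 with sgSetd5 and an edgeR adjusted p of 0.00107. NM_011118.2 had a log2 fold change of 3.82 with the inhibitors, starting from 5.14 CPM in DMSO against 12.5 CPM in sgControl. Of the 10 with the greatest decrease under the inhibitors, 2 had a negative fold change with sgSetd5, and the 1 that was called there was higher. NM_011607.3 had a log2 fold change of 0.38 with sgSetd5, with an edgeR adjusted p of 0.0984. Of the 10 with the greatest increase in sgSetd5, 4 were called higher and 3 were called lower with the inhibitors. Of the 10 with the greatest decrease in sgSetd5, 4 were called lower and 2 were called higher with the inhibitors.

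The 552 accessions higher with the inhibitors were shifted upward as a set with sgSetd5 (limma camera, adjusted p = 0.00245 over 4 sets; adjusted p = 0.00396 with an estimated correlation). Their median log2 fold change there was 0.07, and 59.8% were positive. The other 3 sets did not pass (limma camera, adjusted p = 0.127 each, and adjusted p = 0.631 each with an estimated correlation). Among them, the 528 accessions lower with the inhibitors also leaned upward with sgSetd5, with a median of 0.024 and 55.9% positive. Since that set did not pass, whether an upward lean extends beyond accessions higher with the inhibitors stays open. Across all 9399 accessions the fold changes had a Pearson r of 0.097 and a Spearman rho of 0.076. The jackknife standard error of r over left-out libraries was 0.103. It treats the 12 libraries as 1 sample and ignores the 4 groups, so it does not decide whether r differs from 0. The 114 shared calls in the same direction became 198 without DMSO replicate 1, 55, 62 and 71 without sgControl replicates 1, 2 and 3, and 73, 54 and 67 without sgSetd5 replicates 1, 2 and 3. The 79 in opposite directions became 274, then 39, 39 and 47, then 47, 41 and 40. Without DMSO replicate 1 more shared calls were thus in opposite directions than in the same direction. The lists also changed in size, to 1736 and 1373 calls without DMSO replicate 1. Shared calls expected for lists of those sizes were not computed, so these counts do not show whether the excess grew or shrank. With only the 6 libraries of each comparison, lists of 1865 and 704 shared 139 in the same direction and 116 in opposite directions.

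**Figure D3:**
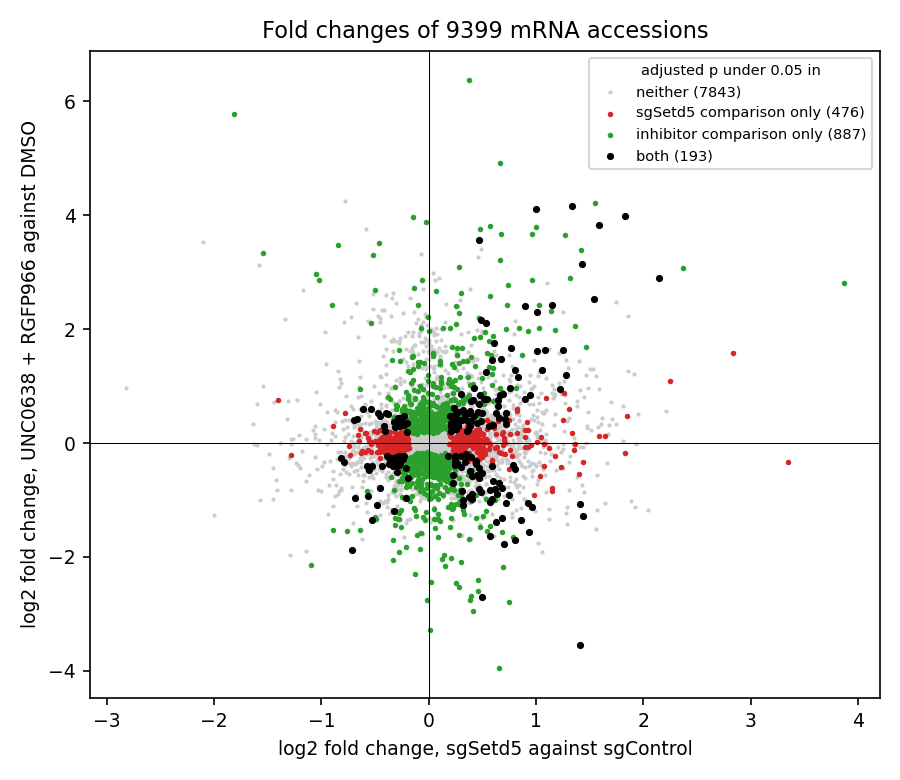
Fitted log2 fold change with sgSetd5 (horizontal) against that with the inhibitors (vertical) for 9399 accessions, a point each, coloured by the comparisons in which they were called. The 193 accessions called in both include 114 with the same sign and 79 with opposite signs.

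The response of an accession to the guide was also tested directly against its response to the inhibitors. The responses differed for 909 accessions (edgeR interaction test, adjusted p under 0.05). They included 32 of the 114 accessions called in the same direction, and the 79 called in opposite directions, which nearly must pass such a test. Of the 476 called only with sgSetd5, 199 passed this test, and of the 887 called only with the inhibitors, 466 did. Without DMSO replicate 1 the count rose to 1909. The responses start from control groups that themselves differed, as given below. A difference in response can therefore not be told apart from a difference between the arms.

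The control groups, sgControl and DMSO, differed at 2115 accessions, 22.5% of those tested (edgeR, adjusted p under 0.05), with 1014 higher and 1101 lower in sgControl. In the fit of all 12 libraries this exceeds the count in either treatment comparison. The order turned with only the 6 libraries compared, at 1387 against 1865 for sgSetd5, with the replicate number as a block in those libraries, at 1129 against 1982, and at 2-fold or more, at 232 against 242 for the inhibitors. Guide delivery, vehicle and any difference in day between the arms cannot be told apart here. The count was 1369 without sgControl replicate 1, 3477 with voom sample weights, and 1014 with the share of the set of 94 accessions as a covariate.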

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

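The tests on the set of 94 accessions, on the difference between the control groups, on matched expression and on set members among shared calls were chosen only after the result was seen; matching on spread and the splits of the libraries were chosen before.

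The responses to Setd5 loss and to the inhibitors differed by an interaction test at 909 accessions. Among them were the 79 accessions called in opposite directions in the treatment comparisons. For these the test adds little, since such accessions nearly must pass it. The control groups also differed, so a difference in response cannot be told apart from a difference between the arms.

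A set of 94 accessions was near 0 in DMSO replicates 1 and 2 and present in the other 10 libraries. Low depth is argued against, because 5254 counts would be drawn in DMSO replicate 2 at the share of DMSO replicate 3, and 10 were seen. Whether the guide or the inhibitors also move its level stays open: the range was 4.44-fold within sgSetd5 and 2.59-fold within the inhibitor group, but without replicate 3 it was 1.31-fold and 1.15-fold. RNA of one other source at different shares is a candidate explanation: over the 9 libraries outside DMSO, the median correlation of a member with the rest of the set was 0.937, against -0.121 for other accessions of matched level. The source stays open, and no biological explanation beyond the groups was tested.

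The control groups differed at 2115 accessions, more than either treatment in the fit of all 12 libraries, but not with only the 6 libraries compared (1387 against 1865 for Setd5 loss), with the replicate block in those (1129 against 1982) or at 2-fold (232 against 242 for the inhibitors). Of the set of 94 accessions 93 were tested and 13 were called here, so its members could not make up the count. Leaving the set out gave 2146, which does not test whether other accessions vary with it. Leaving out DMSO replicates 1 and 2 gave 2256, which decides nothing, since it leaves a DMSO arm of 1 library that is assumed to vary like the other groups and also changes the spread. With the set's share as a covariate the count was 1014, but that share itself differs between the groups. Guide delivery, vehicle and day are confounded with the arm and cannot be told apart, and a biological effect of any of them stays untested.

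Calls shared by both treatments exceeded independent lists. At matched expression 45.9 would be shared in the same direction, and at matched expression and spread 49.0, against 114 observed. Neither property accounts for this pooled excess alone. At matched expression 22.5 would be higher in both, against 79 observed, and 23.5 lower in both, against 35. The excess in the same direction thus lay mostly in accessions higher in both. Members of the set of 94 accessions made up 0% of the edgeR shared calls, which decides nothing, since edgeR called no member in either treatment comparison. In opposite directions 79 were shared against 42.4 at matched expression and spread. Accessions that respond to many perturbations, in either direction, may be among them; that stays open, as does a response common to both treatments.

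For each 3 against 3 comparison there are 10 splits of the 6 libraries, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many calls. The real counts were 669 for Setd5 loss, 1080 for the inhibitors and 2115 for the control groups, and the highest other split gave 0 in each. For the interaction, 2 of 100 splits gave as many as the 909 calls, and the highest other split gave 1070. For shared calls, 1 of 100 splits gave as many as 114 in the same direction (highest other 79), and 2 of 100 gave as many as 79 in opposite directions (highest other 114). For the interaction this share is under 0.05, but the splits do not test whether the real responses differ, since each of the other splits drawn breaks the grouping of at least 1 comparison, except the 1 that gave 1070. For shared calls the splits decide nothing, because other splits of either comparison give 0 calls and so 0 shared calls. The highest other split was the one that keeps the real groups and exchanges the labels of 1 comparison, which exchanges same and opposite directions and turns the interaction into the sum of both effects. Apart from it, the highest were 357 for the interaction and 0 for both kinds of shared calls.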

How the results depend on the processing

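The gene list alternatives were not run, because no list could be tested. Alternatives added after the data were seen are named as such. Directions of the 4 named accessions were kept in every alternative in which they were tested. With library size only, Setd5 loss gave 209 lower. With only the 6 libraries compared, it gave 896 higher and 969 lower, the inhibitors gave 332 lower and the control groups 1387. At least 2-fold left 43 and 2 for Setd5 loss, 141 and 101 for the inhibitors, 232 between the control groups, 222 for the interaction, and 13 shared in the same and 3 in opposite directions. An adjusted p under 0.01 left 135 and 101, 354 and 340, 1134, 463, 46 and 26 in the same order; both follow from the stricter threshold. Of the added alternatives, the set share as a covariate gave 1014 between the control groups. One surrogate variable gave 168 lower for Setd5 loss, 406 calls in all with 251 of the 669 among them, and turned the correlation of fold changes to -0.124. That variable was -0.326, -0.414 and -0.432 in sgSetd5 and -0.121, -0.0835 and 0.181 in sgControl. It may therefore take out part of that contrast. Leaving out DMSO replicates 1 and 2 gave 766 higher and 885 lower for Setd5 loss, 1545 for the interaction, and 141 shared in the same and 196 in opposite directions; the DMSO arm then holds 1 library, which is assumed to vary like the other groups. Voom with sample weights gave 872 and 940 for Setd5 loss, 850 higher for the inhibitors, 3477 between the control groups, 2005 for the interaction, and 217 and 242 shared. Except for the thresholds, the cause was not tested.

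Leaving out each library in turn gave 160 to 879 higher and 103 to 857 lower for Setd5 loss, 434 to 733 and 370 to 681 for the inhibitors, 1369 to 2997 between the control groups, 681 to 1909 for the interaction, 54 to 198 shared in the same and 39 to 274 in opposite directions, and a correlation of 0.044 to 0.158. Without DMSO replicate 1, without DMSO replicates 1 and 2, with the surrogate variable (84 against 83) and with voom sample weights, more shared calls were in opposite directions than in the same direction. Among the fits that leave out 1 library, the highest counts for Setd5 loss, the control groups, the interaction and the shared calls came without DMSO replicate 1. Its chi-square over degrees of freedom was 26.9 against DMSO replicate 2 and 35.8 against DMSO replicate 3, with at most 5.96 among pairs without it. In checks added after the data were seen, the value against DMSO replicate 2 was 21.9 with DMSO replicate 1 thinned to equal depth, and 21.2 without the 100 most abundant accessions. Thinned to equal depth, Setd5 loss gave 677 calls. The correlation of DMSO replicate 1 was 0.990 with DMSO replicate 2, 0.976 with DMSO replicate 3 and at most 0.974 with a library of another group.

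The replicate numbers did not pair the samples in either treatment comparison: correlations of same-numbered deviations were -0.115, 0.00692 and -0.15 for the guides and -0.0729, -0.0265 and -0.274 for the drug arm. Between groups of different arms they ranged from -0.46 to 0.185, and no pair of groups had all 3 above 0.1. With the replicate block and all 12 libraries, Setd5 loss gave 328 higher and 299 lower. With the replicate block in the 6 libraries compared, it gave 935 and 1047, the control groups 1129 and opposite directions 145.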

Other observations

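Without the set of 94 accessions the first principal component held 30.7% of the variance and separated the guide arm, at 16.5 to 22.4, from the drug arm, at -24.6 to -12.4. No accession was at 0 counts in all 3 libraries of one group and at 10 or more in each of the other, in either treatment comparison. Accessions with at least 50 counts in a library and over 2 times the CPM of every other library numbered 6 in sgSetd5 replicate 2, 4 in sgSetd5 replicate 3 and 1 in DMSO replicate 2, and 0 in the other 9 libraries.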
